A study of Mus musculus with 9 samples.

How the data were processed

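Total RNA from the lungs of 9 mice was measured on Agilent arrays of mouse long noncoding RNA and messenger RNA probes, 1 array per mouse. Per the labels, 3 mice were controls (1 male, 2 females), 3 were ageing-model mice (all female) and 3 formed the Codonopsis pilosula intervention group (2 males, 1 female). The model arrays are labelled with D-galactose and sodium nitrite, and the labels of the codonopsis arrays do not repeat these. Per the labels' protocols, RNA was extracted with TRIzol, amplified linearly and labelled with Cy5, so that each array carried 1 sample in the red channel. Images were read with Agilent Feature Extraction, version 10.7 per the submitters' processing notes and version 11.5.1.1 per the file headers. The deposited scanner files give the processed signal intensity of each spot, from which the scanner software had subtracted the background, per the file headers. They also give the median intensities of spot and local background and the software's calls of spots as well above background, as outliers or as saturated. The signal intensities were not normalized between arrays. The deposited value table of the series holds log2 values, 1 per probe name. Its columns for 8 of the arrays shared their whole-number percentiles within 0.001, as quantile normalization gives, and each of its columns had a median of 7.65. These percentiles and the rank correlation with each array's scanner file set its scale. How spots were combined in it is not given in the sources used here.

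Each array held 180880 spots, of which 175906 belonged to 97836 probes and the rest were controls. Of these probes, 39027 were Agilent catalogue probes, for which no gene names were used here. The other 58809 came from collections of noncoding transcripts, with 28773 from NONCODE, 15675 RIKEN cDNA clones, 13019 RefSeq records, 942 Ensembl transcripts, 373 ultraconserved elements and 27 transcripts named in the files. Accessions without versions matched 4658 of the 13019 RefSeq probes to a gene in a RefSeq gene table of mouse assembly GRCm38.p6. Clone names listed there as synonyms matched 1209 of the 15675 RIKEN probes, 654 of them to a protein-coding gene. Such a probe reports a cDNA clone of the locus, not its messenger RNA as such. RefSeq probes report noncoding transcript records, so one matched to a protein-coding gene does not report its messenger RNA as such either. Together 5894 probes had 1 of 5420 symbols, and 888 symbols were established names. No coordinates are given, because the array design was made on another genome build than that table.

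Spots called outliers in brightness or evenness were left out. Between 1.46% and 11.0% of the spots of an array were so called. The log2 processed signals were averaged per probe and reduced by each array's 75th percentile over all probes, since a mean of 63.5% of spots were well above background. Probes were kept if well above background on every array of at least 1 group and unflagged on every array in the fit. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend), with terms for group and sex, two-sided, at a Benjamini-Hochberg adjusted p of 0.05. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 prepared the tables. Differences among the 3 groups were tested with limma's moderated F. A further limma fit added a sex by group term. Gene lists were tested with camera at a preset correlation of 0.01, with 1 probe per gene, the brightest.

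Before the data were examined, the comparisons, the sex term, all 9 arrays, 36 gene lists, the alternatives and the rule for named genes were fixed. After the array of control female 2 was found to be misread, a fit of the other 8 arrays was added, and a fit of 7 arrays without control male 1 as well. The array sets, and the rule that a probe be unflagged on every array in the fit, were settled after array quality and the numbers of calls under many combinations of array set, sex term, slide term and treatment of flagged spots had been seen. They were settled before the values of any gene. The results on 8 and 7 arrays are therefore exploratory. The fit of all 9 arrays is called planned for its arrays and terms, but it too uses the later rule on flagged spots.

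Under the rule for named genes, each comparison takes up to 12 rises and 12 falls among established symbols past the threshold whose sex-adjusted values do not overlap, and the 3 largest rises and falls among transcripts named in the files. Empty places among the 24 go to the smallest unadjusted p among genes changed at least 2-fold, as values and not as calls. Up to 4 members with the smallest p of each list are added. The rule was applied to the fit of 8 arrays. Where a group was not well above background on any array, the brighter group was set against the higher of the dim probe's own signal and the array's lowest signal well above background, and the fold is given as a lower bound.

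The fit was tested on simulated data with the real probe means and spreads of 51472 probes, with 50 probes changed by each fold size. For model against control with 8 arrays, 8% of the 2-fold, 92% of the 4-fold and 100% of the 8-fold changes were recovered, with 17 calls among unchanged probes. With a ninth array whose probes were permuted, 0% of the 4-fold, 4% of the 8-fold and 28% of the 16-fold changes were recovered. For codonopsis against model and codonopsis against control, 96% and 94% of the 4-fold changes were recovered with 8 arrays and 0% with the permuted array. On 8 arrays the calls among unchanged probes made up 10.2%, 11.9% and 9.30% of all calls in the 3 comparisons, more than the adjusted threshold aims at. The simulated 8 arrays were drawn from the mean and spread of each probe. They held no shift shared by many probes of an array, such as the brighter dim probes on the control male's array. The recovery and the calls among unchanged probes therefore do not describe a fit that holds such a shift, as the real fit of 8 arrays does. The number of arrays limits the precision of every value.

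Alternatives covered quantile normalization, the other probe set behind the percentile, normexp background correction with an offset of 50, the deposited table, the filter on dim probes, the trend, array weights, the sex term, female mice, only the groups compared, the slide, the number in the title as a block, each array left out, and other list tests. The mean spot signal that normexp was planned on was not used here, and the median spot signal took its place. Arrays of the same slide were also scanned together, so slide and scan were 1 factor with 3 levels. Slide 1 held the 3 codonopsis arrays and model female 1, slide 2 held model females 2 and 3, control male 1 and control female 1, and slide 3 held control female 2 alone. Labels do not say whether mice of a group shared a cage or litter.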

Results

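Lung RNA of 9 mice was profiled to ask which long noncoding and messenger RNAs differ in an ageing model, and which differ again after an intervention with Codonopsis pilosula, a root used in traditional Chinese medicine. Per the labels, codonopsis was given at 15 g per kg and the title names day 30, while the title of the model arrays names day 42. The model arrays are labelled with D-galactose and sodium nitrite. Each group had 3 mice. Between 59.8% and 68.0% of spots were well above background on 7 of the arrays, and duplicate spots of a probe correlated at r = 0.982 to 0.996 on 8 arrays (across probes, which are not independent replicates). These 7 arrays correlated with each other at r = 0.962 to 0.984.

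Both remaining arrays belonged to the control group. On control female 2, duplicate spots of a probe correlated at r = 0.00316, and its correlation with any other array was at most 0.00891. The scanner software had marked its grid as bad, and also that of model female 3, whose duplicate spots correlated at r = 0.994. On control male 1, 89.4% of spots were well above background, the 5th percentile of signal was 88.5 against 24.1 to 25.7 on the 7 other arrays, and its correlations with them were 0.760 to 0.849. Results are given for all 9 arrays as planned, for 8 arrays without control female 2, and for 7 arrays without either. The last 2 sets were chosen after the data were seen. With 7 arrays the sex term takes up both codonopsis males, so that control female 1 alone stands for the controls and codonopsis female 4 alone for the codonopsis group.

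**Figure D1:**
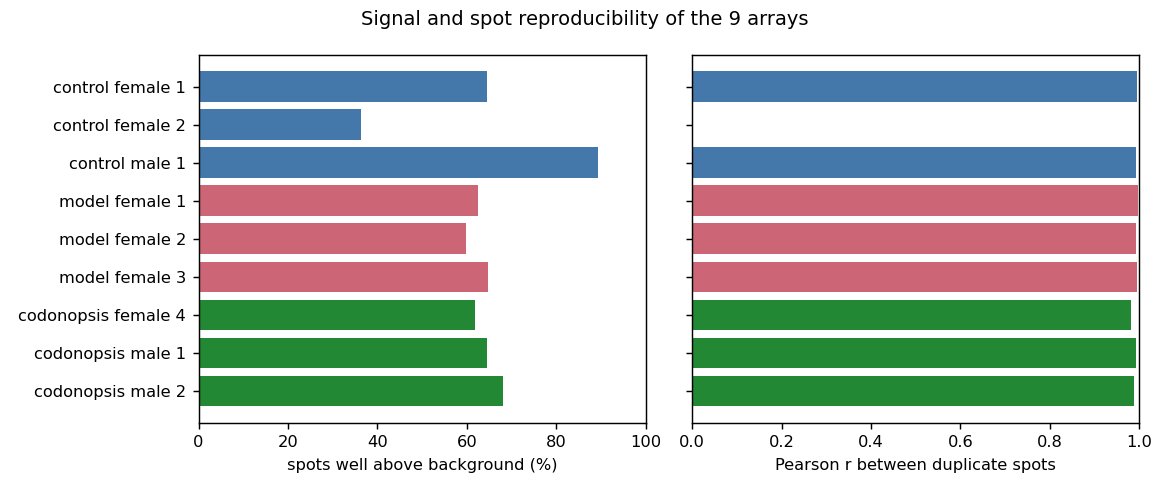
Percent of spots well above background (left) and Pearson r between duplicate spots (right) on each array, 1 bar per mouse, coloured by group (blue control, red model, green codonopsis). Control female 2 has r = 0.00316 between duplicate spots, and control male 1 has 89.4% of spots above background.

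The labels of sex could be checked on the 8 arrays. Of 51472 probes, 7 were at least 8-fold brighter on each of the 3 male arrays than on each of the 5 female arrays, and 4 were at least 8-fold brighter on each female array. Over both directions this made 11 probes, and the highest count among the other of the 56 splits of the arrays into 3 and 5 was 1. The X-linked noncoding RNA Ftx, which lies in the region controlling X inactivation, stood at -0.65 ± 0.07 (SD, n = 3) in males and -0.73 ± 0.27 (SD, n = 5) in females, in log2 units relative to each array's 75th percentile. In limma's fit of all 9 arrays 2 probes passed the threshold for sex, both higher in males, and in the 8-array fit 8213 did, of which 5670 were higher in males. Without control male 1 the sex term called 38 probes.

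The first comparison, of model with control mice, asks which RNAs differ in the ageing model. Entpd1, whose product CD39 breaks down extracellular ATP, was represented by a RIKEN cDNA clone of its locus, which rose 2.94-fold in the 8-array fit (log2 change 1.56, SE 0.28, limma adjusted p = 0.0307). Its level, a group mean not adjusted for sex as the change is, was -1.15 ± 0.22 (SD, n = 2) in controls and 0.50 ± 0.18 (SD, n = 3) in model mice. The predicted long noncoding RNA Gm31617 fell by 2.64 on the log2 scale, which is 6.25-fold lower (SE 0.45, limma adjusted p = 0.0192), and Gm30319 rose by 2.17 on the log2 scale (SE 0.42, limma adjusted p = 0.0376). In the planned fit of all 9 arrays, which holds the misread array, Gm31617 stood at -0.81 (limma adjusted p = 0.643), the Entpd1 clone at 1.67 and Gm30319 at 1.66 (both 0.364). Both Gm transcripts lie outside the rule for named genes and were chosen after their values were seen. Among unnamed probes called with 8 and with 7 arrays, the largest rise was that of NONMMUT057609, at a log2 change of 3.74 (SE 0.63) with 8 arrays and 4.81 with 7. It was well above background on 1 of the 2 control arrays, whose mean was -3.04 ± 2.37 (SD, n = 2), so the size of this rise is poorly determined. The largest fall was that of RefSeq record XR_379625.2, at -2.68 with 8 arrays and -3.31 with 7.

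In all, 163 of 51472 probes passed limma's threshold with 8 arrays, 149 higher and 14 lower in model mice. Catalogue probes made up 112 of the rises and 1 of the falls, and noncoding probes 37 and 13. The median change of all catalogue probes was 0.14 and that of all noncoding probes -0.092, and 0.12 and 0.017 with 7 arrays. The fitted change rose with the signal of the probe (r = 0.41 across probes, which are not independent, and 0.30 with 7 arrays). The split of the calls by class therefore goes with a shift of each class as a whole. The share of 91.4% higher calls was 76.4% with the percentile taken over probes above background on every array, with 207 higher and 64 lower. With all 9 arrays 0 of 46565 probes passed limma's threshold, 5218 had an unadjusted p under 0.05, and the smallest adjusted p was 0.364. With 7 arrays 29 passed, 23 higher and 6 lower, of which 24 were among the 163. Leaving out 1 of the 8 arrays gave 5 calls (without model female 2) to 14910 (without control female 1). The filter on dim probes then rests on control male 1 and kept 76509 probes, and with the probes of the 8-array fit 4018 passed. Without model female 2 the Entpd1 clone, Gm31617 and Gm30319 stood at 1.57, -2.84 and 2.10 (limma adjusted p = 0.168, 0.171 and 0.255). Without control female 1 Gm31617 stood at -1.23 (limma adjusted p = 0.113) and Gm30319 at 3.57 (0.00217), and without codonopsis female 4 the Entpd1 clone had 0.102 and Gm30319 0.155. The Entpd1 clone had 0.0684 without model female 3. With 7 arrays it stood at a log2 change of 1.49 (limma adjusted p = 0.108), Gm31617 at -3.21 (0.0380) and Gm30319 at 1.61 (0.172). No probe passed on 8 arrays when spots flagged as outliers were kept or when the deposited table was used, and 5 passed after quantile normalization, none of these 3 transcripts among them. The Entpd1 clone, Gm31617 and Gm30319 stood at 1.42, -2.78 and 2.03 with flagged spots kept. They stood at 1.64, -2.78 and 2.42 in the deposited table and at 1.73, -2.54 and 2.55 after quantile normalization. Without the sex term the Entpd1 clone, Gm31617 and Gm30319 stood at 1.65, -2.08 and 2.34 (limma adjusted p = 0.0709, 0.1501 and 0.108), and with array weights their limma adjusted p was 0.192, 0.140 and 0.289. In females alone the Entpd1 clone had 0.0815 and Gm30319 0.0558, with only the 2 groups the Entpd1 clone had 0.0602, and Gm30319 had 0.0615 without the trend and 0.0651 with probes flagged on some arrays kept.

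**Figure D2:**
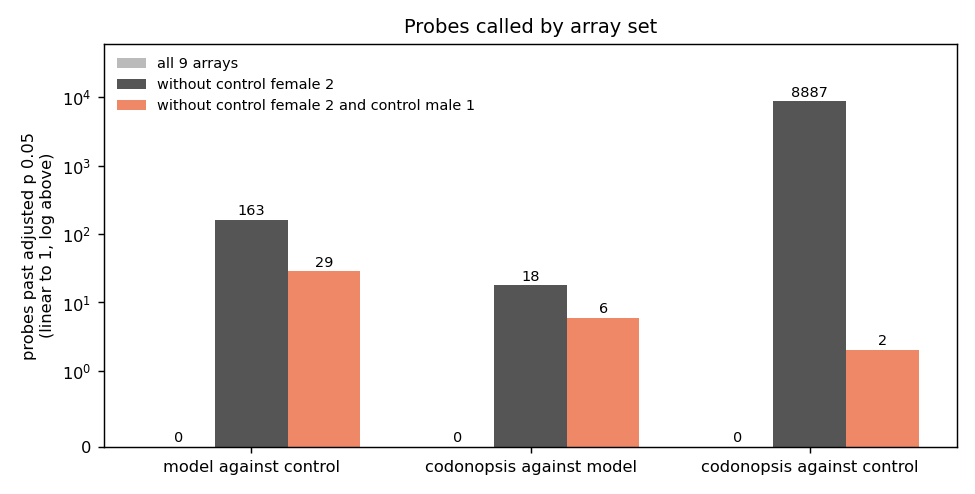
Number of probes past limma's adjusted p of 0.05 in each comparison, with all 9 arrays, without control female 2 and without both doubted control arrays (vertical axis linear to 1 and logarithmic above). The counts are 0, 163 and 29 for model against control, 0, 18 and 6 for codonopsis against model, and 0, 8887 and 2 for codonopsis against control.

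No other established symbol passed in this comparison, so the further genes are given as values from the 8-array fit, none of them past the threshold. A clone of Tnks, which encodes tankyrase, differed by 1.35 in log2 (SE 0.29), Lncppara by 1.85 (SE 0.42), a clone of the phosphatase gene Dusp4 by 1.02 (SE 0.30), a clone of the kinase gene Nek7 by 1.21 (SE 0.36) and a clone of Rgs5 by 1.03 (SE 0.41). Clones of Akap13, an anchoring protein of protein kinase A, and of Prkar2a, a regulatory subunit of that kinase, differed by 1.30 (SE 0.41) and 1.07 (SE 0.33), the latter by 0.70 with 7 arrays. Lower values were those of clones of Slc6a11 at -1.11 (SE 0.47) and Mir100hg at -1.16 (SE 0.49) and of Znf41-ps at -1.20 (SE 0.42), which was -0.62 with 7 arrays. For the first 2 the model group was not well above background on any array, and the control means lay at least 2.11-fold and at least 2.39-fold above the bound for model mice. Without control female 1 the fitted value of Slc6a11 turned to 0.15, so its direction rests on that array. Of the 28 named values of this comparison that had not passed, 12 passed without control female 1, in a fit whose only control is control male 1, assumed to vary like the other groups, and 0 without control male 1. Among the 12 were Akap13 at 2.35 (limma adjusted p = 0.0132), Prkar2a at 1.99 (0.00644), Nek7 at 1.89 (0.0218), Tnks at 1.79 (0.00881) and Znf41-ps at -2.65 (0.00544), while Rgs5 was 0.48 there and did not pass. Lncppara passed without control female 1 (limma adjusted p = 0.0219), without codonopsis male 1 (0.0188), without codonopsis male 2 (0.0150) and without model female 1 (0.00747), and Snhg5 without control female 1 (0.0362) and without model female 1 (0.0459). Without model female 1 Mir100hg was -0.72. Without any other array none of the 28 passed.

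Of the 36 gene lists, 1 had at least 5 named members measured, that of named long noncoding RNAs, with 14. In the 8-array fit 11 of the 14 were higher in model mice, with a median log2 change of 0.27. Limma's camera gave an adjusted p of 0.000296 at the preset correlation and an adjusted p of 0.0524 with an estimated correlation, and limma's fry gave an adjusted p of 0.0749. The adjustment was over the lists tested, and with 1 list it leaves each p as it was. In this comparison the fitted change rose with the signal of the probe (r = 0.41 across all probes). Camera takes no account of signal, so what brightness adds to the list result was not tested. One of the 14 passed when adjusted over the list alone, and likewise over all genes with a symbol. The 4 members with the smallest p were Snhg5, a host of small nucleolar RNAs, at 1.35 (SE 0.35), Lncpint, a noncoding RNA induced by p53, at 0.77 (SE 0.31), Snhg3 at 0.71 (SE 0.33) and Mir22hg, the host of miR-22, at 0.53 (SE 0.28). With 7 arrays Snhg3 stood at 0.45, and without control female 1 Snhg3 at 1.34, Lncpint at 1.18 and Mir22hg at 0.91, none of them past the threshold. In the planned fit of every array camera gave an adjusted p of 0.161, and without both doubted arrays an adjusted p of 0.0292, with an adjusted p of 0.234 at an estimated correlation. A clone of Sod1, the cytosolic superoxide dismutase of the oxidative stress list, differed by 0.25 (SE 0.30), a clone of Hydin of the ciliated cell list by 0.30 (SE 0.30), Mx2 of the interferon list by 0.18 (SE 0.30) and a clone of Synpo2 of the smooth muscle list by 0.01 (SE 0.28), none past the threshold. The RefSeq gene table lists Mx2 as a transcribed pseudogene, and its probe reports a noncoding record. Without the sex term Mx2 was -0.22 and Synpo2 -0.038, and with 7 arrays Hydin was 0.19, Mx2 0.33 and Synpo2 -0.045.

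**Figure D3:**
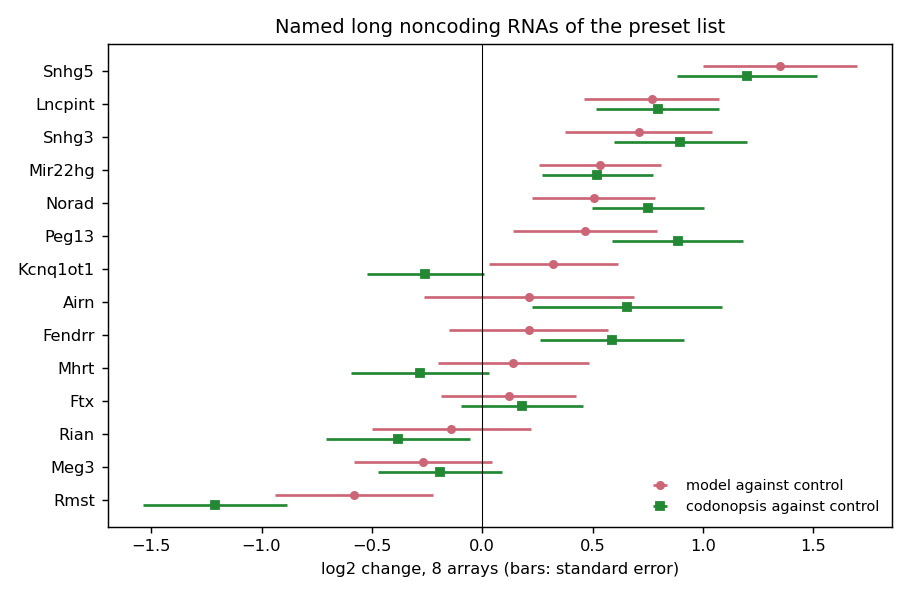
Log2 change of each of the 14 measured members of the preset list of named long noncoding RNAs in the 8-array fit (circles, model against control; squares, codonopsis against control; bars, standard error). Snhg5 lies highest in both, at 1.35 and 1.20, and Rmst lowest, at -0.58 and -1.21.

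The second comparison, of codonopsis with model mice, asks which RNAs differ after the intervention. The labels name day 30 for the codonopsis arrays and day 42 for the model arrays. Only the model labels name D-galactose and sodium nitrite. A difference in day or in these substances cannot be told apart here from the intervention. Gm31617 rose 8.35-fold in the 8-array fit (log2 change 3.06, SE 0.45, limma adjusted p = 0.0347) and by 2.50 in log2 with 7 arrays, where it did not pass. Without codonopsis female 4 the log2 change was 4.48 (limma adjusted p = 0.0224), and without control female 1 it was 2.50, so its size rests on single arrays. With all 9 arrays it was 2.33 and did not pass. That change is adjusted for sex. All codonopsis arrays lay on slide 1 and 2 of the 3 model arrays on slide 2, and with slide as a fixed term the change was 3.00 (limma adjusted p = 0.0524). It was 2.31 without the sex term (limma adjusted p = 0.994) and 3.42 with array weights (0.584). With only the 2 groups its limma adjusted p was 0.141, and with probes flagged on some arrays kept 0.0604. Its unadjusted group means were 0.15 ± 0.42 (SD, n = 3) in model, 2.46 ± 0.51 (SD, n = 3) in codonopsis and 2.23 ± 1.60 (SD, n = 2) in control mice, the controls far apart. The catalogue probe A_55_P2143494, which has no gene name here, was not well above background on any codonopsis or control array, and was at least 4.17-fold lower in codonopsis than in model mice (limma adjusted p = 0.00056), where it stood at -0.45 ± 0.48 (SD, n = 3). It also passed with 7 arrays, and with slide as a fixed term (limma adjusted p = 0.0029). No gene with an established symbol passed.

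In all, 18 of 51472 probes passed limma's threshold with 8 arrays, 8 higher and 10 lower, of which 6 were catalogue and 12 noncoding probes. The split depended on the processing, with 9 higher and 5 lower after normexp background correction, and 26 higher and 34 lower with the percentile taken over probes above background on every array. Leaving out 1 of the 8 arrays gave 6 calls (without control male 1) to 1890 (without codonopsis female 4). In the simulation of this comparison, which also held changed probes, 21 calls fell among unchanged probes, which was 11.9% of the calls made. The 21 is therefore not a count to set against the 18. Over the 9 arrays 0 passed and 342 had an unadjusted p under 0.05 in limma's fit. With 7 arrays 6 passed, 5 higher and 1 lower, 1 of them among the 18, and Gm31617 then had a limma adjusted p of 0.151, and 0.130 without model female 2. A fit of the 6 codonopsis and model arrays called 7 with the background filter taken over these arrays, and 6 with the filter taken over all 3 groups. With flagged spots kept, with the deposited table and with quantile normalization, 0 passed on 8 arrays. All model mice were female, so the sex term rests on the other groups, control male 1 among them. Through that term control male 1 enters this comparison on 8 arrays. The fitted change rose with the signal of the probe (r = 0.38 across probes, which are not independent, and 0.21 with 7 arrays). The median change of all noncoding probes was -0.108 with 8 arrays and 0.0092 with 7, and that of catalogue probes 0.055 and 0.058.

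As values not past the threshold, Mirt2 differed by -1.81 (SE 0.52), Rbfaos by -1.10 (SE 0.39) and a clone of Sdhaf3, an assembly factor of succinate dehydrogenase, by 1.01 (SE 0.45). Rbfaos was well above background on 1 of 3 codonopsis arrays and was -1.82 without codonopsis female 4. Sdhaf3 was so on 2 of 3 model arrays. With 7 arrays Mirt2 was -1.14 and Sdhaf3 0.41, and without codonopsis female 4 Mirt2 was -3.47 and Sdhaf3 2.51, and both passed (limma adjusted p = 0.0253 and 0.0337). Vmn1r-ps79 differed by -1.21 (SE 0.51, limma adjusted p = 0.788), by -0.54 without codonopsis female 4 and by -1.80 without model female 1, the only left-out array without which it passed (limma adjusted p = 0.0440). Mirt2 was not well above background on any codonopsis array, and was at least 1.33-fold brighter in model mice. Within the list of named long noncoding RNAs 8 of the 14 members were higher, with a median log2 change of 0.04. Camera gave an adjusted p of 0.256. With 7 arrays 6 of the 14 were higher, with a median of -0.086 and an adjusted p of 0.328 from camera, so the sign of the median turned without control male 1. With all 9 arrays 6 were higher, with a median of -0.085, while camera put the list upward (adjusted p = 0.279). Kcnq1ot1 differed by -0.58 (SE 0.29), Peg13 by 0.42 (SE 0.33), Mhrt by -0.42 (SE 0.34) and Rmst by -0.63 (SE 0.36). The Sod1 clone differed by -0.14 (SE 0.30), that of Hydin by 0.48 (SE 0.30), Mx2 by -0.47 (SE 0.30) and the Synpo2 clone by 0.15 (SE 0.28). The signs of Vmn1r-ps79, Rmst, Mhrt and Mx2 rest on the sex term, without which they were 0.45, 0.37, 0.075 and 0.068. That of Sod1 turned to 0.069 after quantile normalization. With 7 arrays Sod1 was -0.080 and Synpo2 0.098.

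Whether probes that differ in the model move the other way after the intervention was asked of both comparisons together. The difference in the day and substances named by the labels applies here as well. In the 8-array fit 8 probes passed limma's threshold in both with opposite signs, 5 lower and 3 higher in model mice, Gm31617 and A_55_P2143494 among them. Independent lists of these sizes would share 0.0311 probes, and simulated unchanged groups, which share the model arrays, gave a mean of 0.1 over 20 simulations. Both figures take probes as independent, and without real effects few probes can pass, so a low simulated count follows from the setting. Gm31617 and XR_379625.2 had nearly the same changes (-2.64 and 3.06, and -2.68 and 3.20). Whether the 8 probes are separate signals was not tested. With 9 and with 7 arrays 0 probes did so. Across all probes the changes of both comparisons had a covariance of 0.0293 with 8 arrays, beside -0.0683 in the simulations, and of -0.00986 with 7 arrays, beside -0.0285. Opposite signs held for 39.8% of all probes with 8 arrays, beside 70.1% simulated, and for 50.3% with 7, beside 58.1%. Taken over all probes, the changes thus showed no general move back. Of the 163 probes called for model against control, 123 had opposite signs, but picking them through the shared model arrays favours that. With slide as a fixed term 1 of the 8 probes, A_55_P2143494, still passed in both with opposite signs. The others kept opposite signs there, as Gm31617 at -2.67 and 3.00 in log2. For codonopsis against model NONMMUT055706 shrank from -2.35 to -1.65. With 7 arrays all 8 also kept both signs, Gm31617 at -3.21 and 2.50, in a fit with 1 array each for control and codonopsis. Part of the excess over independent lists may come from the shared model arrays, which are too few to split, and the simulations hold that sharing but no real effects.

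The third comparison asks how far mice of the codonopsis group differ from control mice. In the 8-array fit, clones of Eml1, a microtubule-associated protein, and of Dpf2 rose 3.41-fold and 3.34-fold (log2 change 1.77, SE 0.35 and 1.74, SE 0.37). Clones of Akap13 and Prkar2a rose 3.08-fold and 3.01-fold (SE 0.38 and 0.30 in log2). Further rises were those of Lncppara at 2.76-fold, the Tnks clone at 2.69-fold and Rpph1, the RNA subunit of ribonuclease P, at 2.67-fold. The Entpd1 clone rose 2.59-fold, and clones of Thap3, Tbc1d20 and the antiviral gene Zc3hav1 rose 2.55-fold, 2.52-fold and 2.44-fold. A noncoding RefSeq record of the Bcor locus rose 2.39-fold. Dpf2, Thap3 and Bcor were well above background on 1 of the 2 control arrays. These 12 had limma adjusted p of 0.00477 (Tnks) to 0.0339 (Bcor). Without control male 1 their log2 changes were 0.66 for Eml1, 0.57 for Dpf2, 0.78 for Akap13, 0.85 for Prkar2a, 1.03 for Lncppara, 1.07 for Tnks, 0.34 for Rpph1, 1.25 for Entpd1, 1.16 for Thap3, 0.81 for Tbc1d20, 0.70 for Zc3hav1 and 0.19 for Bcor. Without control female 1, and likewise without codonopsis female 4, Dpf2 was 2.62, Rpph1 2.22 and Bcor 2.06.

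Among the falls, the pseudogene Vmn1r-ps79 was 4.73-fold lower and a clone of Fbxw16 4.67-fold lower, each well above background on 2 of 3 codonopsis arrays, as were Ptprtos, Nxpe4 and Rmst. The Mir100hg clone and Rbfaos were so on only 1 of the 3, and their folds rest mostly on signals not well above background. Ptprtos was 3.55-fold lower, the Mir100hg clone 3.13-fold lower, a clone of Nxpe4 3.06-fold lower and the X-linked noncoding RNA Firre 2.58-fold lower. Rbfaos was 2.43-fold lower, a noncoding RefSeq record of Pex26, a peroxisome gene, 2.38-fold lower, Rmst 2.31-fold lower and Znf41-ps 2.30-fold lower. Cdr1os and Olfr1372-ps1 were not well above background on any codonopsis array and were at least 1.17-fold and at least 1.84-fold lower. These 12 had limma adjusted p of 0.00428 (Fbxw16) to 0.0412 (Znf41-ps). Without control male 1 the log2 change was -0.20 for Firre, -0.045 for Znf41-ps, -0.70 for Rbfaos, -0.81 for Rmst and -2.43 for Nxpe4. Without control female 1, and likewise without codonopsis female 4, it was -2.24 for Firre, -2.07 for Znf41-ps and -0.9997 for Nxpe4, the last no longer past the threshold (limma adjusted p = 0.0735 and 0.114). Without codonopsis female 4 Vmn1r-ps79 and Cdr1os did not pass either (limma adjusted p = 0.0533 and 0.106). Without codonopsis male 1 Bcor, Rbfaos, Rmst and Znf41-ps did not pass (0.101, 0.0780, 0.0615 and 0.0710), without codonopsis male 2 Znf41-ps did not (0.0780), and without model female 2 Bcor, Firre and Znf41-ps did not (0.0653, 0.0597 and 0.0741). Control values were far apart for many of them, as for Firre at 0.24 ± 1.83 (SD, n = 2) and Eml1 at 0.11 ± 1.38 (SD, n = 2).

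In all, 8887 of 51472 probes passed limma's threshold with 8 arrays, 5958 higher and 2929 lower in codonopsis mice. Of the catalogue probes 4762 were higher and 1054 lower, and of the noncoding probes 1196 were higher and 1875 lower. The fitted change rose with the signal of the probe (r = 0.52 across probes, which are not independent, and 0.37 with 7 arrays). The median change of all noncoding probes was -0.20 with 8 arrays and 0.044 with 7, and that of catalogue probes 0.18 and 0.20. Over the 9 arrays 0 passed and 4893 had an unadjusted p under 0.05 in limma's fit, and with 7 arrays, without control male 1, 2 passed. Of the 25 named calls 17 were tested with all 9 arrays, with limma adjusted p of 0.474 to 0.612, and Prkar2a then stood at 2.42, Rmst at -2.43, Tbc1d20 at 0.81 and Znf41-ps at -0.71. None of the 25 named calls passed with 7 arrays, where the log2 change of 11 was over 1.5 times smaller and that of 1 over 1.5 times larger, and with no sex term 0 probes passed on 8 arrays. With any other of the 8 arrays left out 21 (without codonopsis male 1) to 25 of them passed. With array weights 4 of the 25 passed, and 12 with the deposited values. All codonopsis arrays lay on slide 1 and both controls on slide 2, and with slide as a fixed term 47 probes passed on 8 arrays and 0 of the 25 named calls. Leaving out control female 1 gave 37552 calls of 76509 probes, and 15335 with the probes of the 8-array fit. That fit sets both codonopsis males against control male 1, assumed to vary like the other groups. The split of 67.0% higher calls was 82.1% after quantile normalization and 46.2% with the percentile taken over probes above background on every array, which moved the median change of all probes from -0.06 to 0.06 and -0.23.

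Within the list of named long noncoding RNAs 9 of 14 were higher with 8 arrays, with a median log2 change of 0.55. What the rise of the change with signal adds to this list result was not tested. Camera gave an adjusted p of 0.000227 and, with an estimated correlation, an adjusted p of 0.0497. The latter was 0.0614 with the mean of all probes of a gene, and limma's fry gave an adjusted p of 0.0721. When adjusted over the list alone 6 members passed, as over all genes with a symbol. Against all probes 2 members passed, Snhg5, which rose 2.30-fold (SE 0.32 in log2, limma adjusted p = 0.0183), and Rmst, which fell by 1.21 in log2 (SE 0.33, limma adjusted p = 0.0201). Snhg3 differed by 0.90 (SE 0.30) and Peg13 by 0.89 (SE 0.30), and with 7 arrays Snhg3 by 0.39. In the planned fit, which holds the misread array, this was the only call of the list test, with an adjusted p of 0.0186 from camera, and an adjusted p of 0.0544 with an estimated correlation. Without both doubted arrays camera gave an adjusted p of 0.272. The Hydin clone differed by 0.78 (SE 0.27), that of Sod1 by 0.11 (SE 0.27), Mx2 by -0.29 (SE 0.27) and the Synpo2 clone by 0.16 (SE 0.25), none past the threshold. With the percentile taken over probes above background on every array Sod1 was -0.052 and Synpo2 -0.00714, and with 7 arrays Sod1 was 0.23, Mx2 0.0042 and Synpo2 0.053.

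Over the 3 groups at once, limma's F test called 0 probes with 9 arrays, 4864 with 8 and 20 with 7. Slide and group overlapped in part. On slide 2 the sex term takes up control male 1, so model females 2 and 3 stand against control female 1 alone. The Entpd1 clone differed there by 1.58, Snhg5 by 1.43 and the list of named long noncoding RNAs by a median of 0.34, with an adjusted p of 0.0592 from camera at the preset correlation. Limma called 623 of 53128 probes there with 1 residual degree of freedom. On slide 1 codonopsis against model rests on codonopsis female 4 and model female 1, with 1 array for each group, and limma called 0 of 54141 probes, with 4699 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0759. In both fits a lone array is assumed to vary like the other groups. Codonopsis and control arrays shared no slide.

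**Figure D4:**
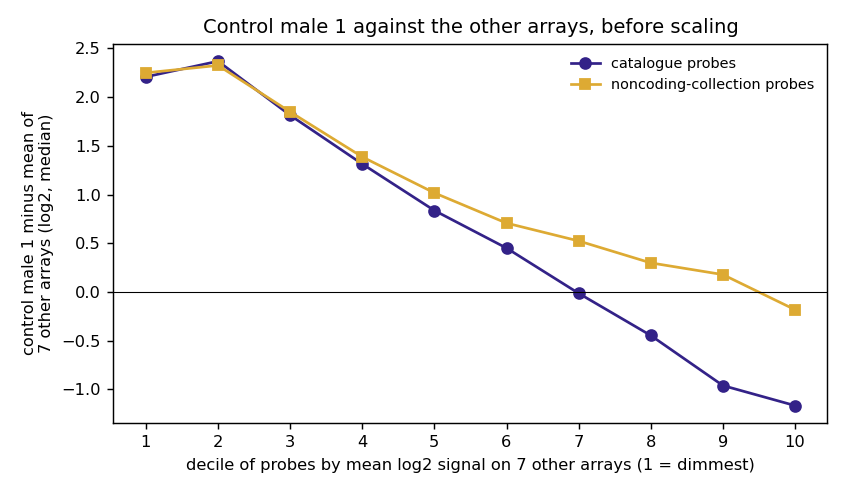
Median log2 difference of control male 1 from the mean of 7 other arrays, before scaling between arrays, in deciles of probes ordered by their mean log2 signal on those arrays, for catalogue probes (circles) and noncoding-collection probes (squares). In the dimmest decile the differences are 2.21 and 2.25, and in the brightest -1.17 and -0.18.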

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

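The tests of the 2 control arrays and of the dependence on control male 1 were chosen only after the results were seen. Of the tests on other splits of the arrays, that on the 8 arrays was set before its result.

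In limma's fit of 8 arrays with a sex by group term, 2 probes showed a difference of the codonopsis effect between the sexes, Gm36036 at -4.04 in log2 (adjusted p = 0.0473) and NONMMUT007531 at -4.57 (adjusted p = 0.0367). That difference rests on 1 array each for control male 1, control female 1 and codonopsis female 4. Only the 2 codonopsis males are replicated, and with the 3 model arrays they give the whole spread. NONMMUT007531 stood at 0.47 on control male 1, -1.41 on control female 1, -1.01 in the codonopsis males and 1.68 on codonopsis female 4. Gm36036 stood at 0.26, -1.32, -0.86 and 1.59. In the 8-array fit with this term 8695 of 51472 probes had an unadjusted p under 0.05, and with all 9 arrays 0 probes passed in limma's fit and 830 had an unadjusted p under 0.05.

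Control female 2 was unrelated to every other array as deposited. A failed hybridisation is argued against by 156 of 476 blocks of spots, which matched the mean of 4 female arrays at r above 0.9 with a common shift of 2 rows and 1 column. A candidate explanation is a scan grid that lay off the spots, since the correlation of the whole array with those 4 arrays was 0.0181 as read and 0.483 at that shift, against 0.163 at the next best shift. Over all 476 blocks the median r at the best shift was 0.706. The best shift varied over the array, as with 1 row and 0 columns in some blocks. Moving spots to the probe under them was possible in 160 blocks, for 46350 probes. For the 7642 of these with both spots moved, duplicate spots then correlated at r = 0.976. Blocks were kept for matching the other arrays, so this last value is partly a product of that choice, and whether the sample is the labelled one stays open.

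Control male 1 had brighter dim probes and dimmer bright probes than the 7 other arrays. A background raised on spots beyond their surroundings over the whole array is argued against by its negative control spots. Their median net signal was -7 against -6.75 to -2 on the others. Net signal is spot minus local background, so a background raised alike in both cancels in it and was not tested. Sex is argued against by the codonopsis males, whose larger shift in the dimmest 3 deciles of probes was 0.184 in log2, against 2.13. Signal added alike to every mouse sequence, as contaminating genomic DNA could give, would not by itself dim bright probes. The brightest decile was -0.673 in log2 from the 7 other arrays, against -0.27 to 0.24 for each of these from the rest. By class it was -1.17 for catalogue and -0.18 for noncoding probes. These signals were not scaled between arrays. The bright decile thus argues only against added signal with nothing else changed, mainly in catalogue probes. It cannot decide whether such DNA was present. For the dim probes added signal stays open, with a median extra signal in the dimmest decile of 0.574 of that in the fifth. Unspliced RNA, which was not tested, and a biological difference of the only control male stay open as well.

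The 8887 calls of codonopsis against control on 8 arrays fell to 2 without control male 1, in a fit that sets codonopsis female 4 against control female 1 alone. A loss of replication alone is argued against, since the changes of 8 arrays with the standard errors of 7 called 1349 probes, but those errors by themselves took more calls than the changes of 7 arrays with the errors of 8, which left 1663. The values of control male 1 are a candidate explanation: over all 8887 calls, each signed by its direction, the median deviation from the mean of the model arrays was -1.98 on control male 1 and -0.48 on control female 1, a ratio of 0.242, and -0.38 to 0.21 on the codonopsis arrays. The calls and their directions came from a contrast that holds control male 1, so its large deviation is partly a product of that choice. The median call had 0.569 of its 8-array change without control male 1. It had 1.32 times that change without control female 1, and likewise without codonopsis female 4. The first of these fits rests on females alone and the others on males alone, so the ratios do not single out control male 1. A difference peculiar to the control male, and a smaller difference between the groups, stay open.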

How the results depend on the processing

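All settings on 8 or 7 arrays, the reassigned array and both treatments of flagged spots were chosen after seeing the data. The rest were planned, apart from the later rule on flagged spots that they use. The cause of a change was not tested unless a sentence gives it. With all 9 arrays, quantile normalization, the other percentile set, the deposited table, the filter to probes above background on all arrays, no trend and both treatments of flagged spots left 0 calls in each comparison and 0 for sex. Without a filter on dim probes sex had 4. Array weights gave 82 probes for model against control (59 catalogue, 23 noncoding), 1 catalogue probe for each codonopsis comparison, 73 among the 3 groups, 10 for sex and 1 in opposite directions. Slide as a random block gave 82 (47 and 35), 1 and 1 (both catalogue), 23 among the groups, 2798 for sex, 1 in opposite directions and 3 for sex by group. Slide as a fixed term, which gives the misread array a term of its own, gave 347 (223 and 124), 13 (4 and 9) and 32 (21 and 11), then 226, 6712, 2 and 6. Without the sex term codonopsis against model had 1 catalogue probe, and with only the 2 groups 6 (2 catalogue, 4 noncoding). Unadjusted p with a 2-fold change gave 4819, 281, 4384 and, for sex, 3851 probes.

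The 8 arrays gave 163 (113 catalogue, 50 noncoding), 18 (6 and 12) and 8887 (5816 and 3071) calls, 4864 among the groups, 8213 for sex and 8 in opposite directions. The 7 arrays gave 29 (18 and 11), 6 (2 and 4) and 2 (1 and 1), then 20, 38 and 0. With slide as a fixed term, 7 arrays gave 32 (18 and 14), 8 (2 and 6) and 1 (noncoding), then 23, 902 and 1. With no sex term they gave 12 (8 and 4), 1 (catalogue), 1 (noncoding) and 4 among the groups. Reassigning the spots of control female 2 left 23361 probes, with 0 calls in each comparison and 7 for sex, and 4 for sex without control male 1 as well.

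Only 1 list was tested, that of named long noncoding RNAs, so its counts are numbers of comparisons. It passed in 1 comparison as planned, and in 0 with the other percentile set, with female mice, with an estimated correlation and with 7 arrays and slide. It passed in 2 comparisons without a filter, with array weights, with no sex term, slide as a fixed term, fry, 8 arrays, 7 arrays without sex, and the reassigned array without control male 1. It was not run with a random block. The count of 2 with fry is that of all 9 arrays, and on 8 arrays limma's fry gave an adjusted p of 0.0749, 0.865 and 0.0721 in the 3 comparisons.

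On 8 arrays, the calls of model against control, codonopsis against model and codonopsis against control were 5, 0 and 8933 after quantile normalization, 271, 60 and 9786 with the other percentile set, 0, 0 and 3814 in the deposited table and 461, 105 and 24054 without a filter. They were 3, 0 and 1033 with array weights, 14, 1 and 0 without the sex term, 116, 109 and 76 in females, 369, 20 and 47 with slide as a fixed term, and 0, 0 and 14799 with flagged spots kept. Codonopsis against model had 9 with probes above background on all arrays, 9 with probes flagged on some arrays kept and 6 with only the 2 groups. Unadjusted p with a 2-fold change gave 2944 and 1177 for the first 2 comparisons.

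Numbers in the titles gave 2 pairs among the 8 arrays, with correlations of 0.297 and 0.208 between deviations from group means, too few to show pairing. With this number as a replicate block, all 9 arrays gave 0 calls in each comparison, and 8 arrays gave 335, 19 and 14227.

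Leaving out each of the 9 arrays gave 0 to 19371 calls for model against control (catalogue 0 to 9363, noncoding 0 to 10008), 0 to 18 for codonopsis against model (0 to 6 and 0 to 12) and 0 to 9004 for codonopsis against control (0 to 5816 and 0 to 4128). Among the groups it gave 0 to 11062, for sex 0 to 8213, in opposite directions 0 to 8, for sex by group 0 to 33793 and the list passed in 0 to 2 comparisons. The highest counts of probes came without control female 1 or control female 2, and the list passed in 2 comparisons without control female 2 and without codonopsis female 4. On 8 arrays the ranges were 5 (without model female 2) to 14910 (without control female 1), 6 (without control male 1) to 1890 (without codonopsis female 4) and 2 (without control male 1) to 37552 (without control female 1). Without control female 1 the filter on dim probes rests on control male 1 and kept 76509 probes, and with the probes of the 8-array fit the counts were 4018 for model against control and 15335 for codonopsis against control. A group left with 1 array is assumed to vary like the others.

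None of the 25 named calls of codonopsis against control turned sign in any setting run on them. None of the 25 passed without the sex term, in females, with slide as a fixed term or on 7 arrays, nor did any of the 17 tested with all 9 arrays. Signs turned for these values, which had not passed. Sod1 was 0.069 (quantile) and 0.060 (deposited table) for codonopsis against model, and -0.052 and -0.051 for codonopsis against control with the other percentile set and with flagged spots. Synpo2, model against control, was -0.082 (quantile), -0.11 (other percentile set), -0.24 (deposited table), -0.038 (no sex term), -0.045 (females, only the 2 groups, 7 arrays), -0.040 (replicate block), -0.13 (flagged spots) and -0.059 (mean of all probes), and -0.069 to 0.14 with an array left out. For codonopsis against control Synpo2 was -0.00714 (other percentile set), -0.16 (deposited table) and -0.00593 (flagged spots). Without the sex term, codonopsis against model was 0.69 for Fbxw16, 0.45 for Vmn1r-ps79, 0.068 for Mx2, 0.37 for Rmst and 0.075 for Mhrt, and Mx2 was -0.22 for model against control. Mx2, codonopsis against control, was 0.0042 in females and on 7 arrays, and -0.51 to 0.0042 with an array left out. With an array left out, model against control was -0.18 to 2.15 for Mirt2, -1.62 to 0.15 for Slc6a11 and -0.19 to 0.33 for Mx2. With all 9 arrays, model against control was -0.90 for Mirt2 and -1.90 for Mx2, and codonopsis against model 0.36 for Mx2, -0.47 for Synpo2 and 0.18 for Rmst. The median of the list of named long noncoding RNAs for codonopsis against model was -0.085 with 9 arrays, 0.044 with 8 and -0.086 with 7. Signal over background limits the values of the probes said not to be well above it.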

Other observations

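Of the tests of other splits of the arrays, those on all 9 arrays were chosen when their real counts were known. With all 9 arrays the real split gave 0 calls in each comparison, and so did 10 of the 10 splits for model against control, 10 of 10 for codonopsis against model and 9 of the 9 that could be fitted for codonopsis against control, with a highest other count of 0. So few splits cannot give a share under 0.05. Over the 3 groups, 100 of 100 splits gave as many as the real count of 0, with a highest other count of 0. Any split reaches a count of 0, so these tests on all 9 arrays decide nothing about chance. On 8 arrays the 18 calls of codonopsis against model were reached by 1 of 10 splits, the real one, and the highest other count was 3, again with too few splits for a share under 0.05.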
